A study of Mus musculus with 12 samples.

How the data were processed

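RNA was measured in 12 libraries of NIH-3T3 cells at passages 5 to 9, grown in DMEM with 10% FBS, per the labels. The groups carried the empty pLX307 vector, KRAS G12V, SOS1 N233Y or SOS1 WT, each with 3 libraries that the design text calls biological replicates. RNA was extracted with RNeasy and made into libraries with a strand-marking kit (NEBNext Ultra Directional), per the labels' protocols. The deposited values are raw counts of reads per Ensembl gene, 1 table per library, which the authors made with STAR and HTSeq on GRCm38, per the submitters' processing notes. Versions, the annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping or antisense gene may not have been told apart. Reads that align to several places are not counted in genes, so genes with near-identical copies are undercounted.

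Each table held 50686 gene IDs and 5 summary lines, which were kept out of library sizes and tests. Per 100 reads counted in genes, the summary lines held 3.91 to 5.67 reads in no gene, 5.61 to 5.99 in more than 1 gene and 16.8 to 20.5 aligned to more than 1 place. Names, positions and biotypes came from GENCODE vM21 (GRCm38), which held 50462 of the IDs, and 224 had no match. Counts in genes were 1112283, 874073 and 1088882 in vector, 1187497, 1028437 and 540462 in SOS1 WT, 755727, 1070254 and 2893611 in SOS1 N233Y and 1144725, 1137624 and 1861161 in KRAS G12V. With 3 counts as the floor, these depths give a lower limit of 1.04 to 5.55 CPM in a single library. Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom of 1.57 to 2.76, so no library was counted as a copy of another.

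Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), using the quasi-likelihood test with robust fitting on all 12 libraries together and 1 coefficient per group. Fitting the groups together gives a shared estimate of the spread. Libraries were scaled by TMM, and filterByExpr (minimum count 10, minimum total 15) left 9792 genes. Adjusted p-values are Benjamini-Hochberg values over those genes, with a threshold of 0.05, and "called" means past it. Log2 CPM for principal components, distances and plots used a prior count of 2. The 6 pairs of groups were compared, together with a test of any difference among the 4 groups. The likeness of profiles was compared with 100 simulated sets of unchanged groups drawn around the same libraries, and the overlap of calls with 20 sets. Plots were drawn with matplotlib 3.10.9.

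The 32 gene lists covered ERK pathway output, ERK feedback and delayed early genes, immediate early genes, EGF receptor ligands and growth factors, growth factor receptors and RAS pathway components. Further lists were MYC targets and ribosome biogenesis, DNA replication and S phase, mitosis, p53 targets, glycolysis and glucose uptake, cholesterol synthesis and uptake, fatty acid synthesis, the ATF4 and unfolded protein response and NRF2 targets. The others were fibroblast extracellular matrix, contractile and SRF-MRTF targets, YAP-TEAD targets, TGF-beta response, matrix proteases and inhibitors, cytokines and chemokines, interferon-stimulated genes, integrins and cell adhesion, EMT regulators, mitochondrially encoded genes and cytosolic ribosomal proteins. Markers of adipocytes, skeletal muscle, bone and cartilage, epithelium, endothelium and macrophages stood for other cell types. The 26 lists with at least 5 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over 156 tests. Of the 66 calls, 0 held with an estimated correlation, whose adjusted p is given beside each called list. Medians of lists were identical with members at 0 counts set to their bound.

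The rule for the genes named was fixed, with the lists, comparisons and alternatives, before the data were examined. It took Sos1 and Kras. In each comparison it then took called protein-coding genes with a mean of at least 1 CPM and no overlap between the libraries of the 2 groups, which chance gives in 10% of genes for 3 against 3. Of these, the 8 highest and 8 lowest by log2 fold change were named for KRAS G12V against vector, SOS1 N233Y against vector and SOS1 N233Y against SOS1 WT, and the 5 highest and 5 lowest for the others. Up to 4 called members of each list were taken by size of change, from which the text gives examples, and a gene named in 1 comparison could be given in others. Clone names and Gm numbers were left out.

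The test was tried on simulated counts with the same libraries and 200 changed genes among 9792. It recovered 76%, 85%, 72%, 76%, 76% and 82% of 2-fold changes for KRAS G12V, SOS1 N233Y and SOS1 WT against vector, SOS1 N233Y against SOS1 WT and KRAS G12V against SOS1 N233Y and SOS1 WT. For 4-fold changes it recovered 92%, 99%, 95%, 98%, 96% and 100%. Of its calls in the same simulations, 4%, 8.46%, 7.73%, 6.95%, 6.52% and 9% were genes that had not been changed, which is more than the threshold of 0.05 allows on average in 5 of the 6. The alternatives were DESeq2 size factors (RLE) in the edgeR fit, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5 (glmTreat), other filters on low counts, fits of the compared groups alone and the replicate number as a block. Each library was also left out in turn, and the lists were tested with fry. Thinning to the shallowest library and leaving out the shallowest and deepest libraries were added after seeing the data.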

Results

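Gene expression was measured by RNA sequencing in NIH-3T3 cells, an established line of mouse embryonic fibroblasts. The cells carried an empty vector, wild-type SOS1 (SOS1 WT), SOS1 with the N233Y substitution (SOS1 N233Y) or KRAS with the G12V substitution (KRAS G12V). SOS1 is the exchange factor that loads RAS proteins with GTP, and G12V is an oncogenic substitution that keeps KRAS in its active form. The comparisons ask what each construct changed, what N233Y changed beyond wild-type SOS1, and how far SOS1 N233Y and KRAS G12V cells were alike. Each group had 3 biological replicates, so that 12 libraries entered the analysis. Reads counted in genes ran from 540462 in SOS1 WT 3 to 2893611 in SOS1 N233Y 3, and 9792 genes passed the filter on low counts. Below, a level is a normalised read count in CPM, given as mean ± SD over n = 3 libraries of a group, and a change is a log2 fold change with its standard error (SE) from the same libraries. Values in brackets after a gene are its log2 fold change, SE and adjusted p. For a gene with no count in 1 of the groups, the fold is a lower bound against 3 counts over that group, and for a gene with 1 to 3 counts it is a ratio of pooled counts with its exact 95% counting interval. Such bounds and intervals cover counting error only. Where leaving out 1 library moved such a value by over 1.5 times, the value without it is given. If no count was left in the lower group, that value is a bound against 3 counts.

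Reads of the introduced genes followed the labels. Sos1 (ENSMUSG00000024241; GRCm38 chromosome 17, 80393751 to 80480453, minus strand) stood at 77.8 ± 12.9 CPM in vector cells, 267 ± 54.4 in SOS1 WT cells and 654 ± 219.7 in SOS1 N233Y cells, with 69.1 ± 8.85 in KRAS G12V cells. It was higher than in vector in SOS1 WT cells (1.81, SE 0.30, edgeR adjusted p = 0.00671) and in SOS1 N233Y cells (3.05, SE 0.29, edgeR adjusted p = 1.75e-05). SOS1 N233Y cells also had more Sos1 reads than SOS1 WT cells (1.24, SE 0.25, edgeR adjusted p = 0.00851), with 411 to 838 CPM per library against 205 to 307. Kras (ENSMUSG00000030265; GRCm38 chromosome 6, 145216699 to 145250239, minus strand) stood at 172 ± 34.2 CPM in KRAS G12V cells and 75.6 ± 8.52 in vector cells (1.19, SE 0.15, edgeR adjusted p = 9.62e-08). In SOS1 WT and SOS1 N233Y cells its log2 fold changes against vector were -0.14 (SE 0.17, edgeR adjusted p = 0.731) and 0.11 (SE 0.16, edgeR adjusted p = 0.692). The labels do not give the species of the introduced sequences. If they were human, only reads close enough to the mouse gene to align would be counted, so the rise checks the label and its size does not measure the construct.

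**Figure D1:**
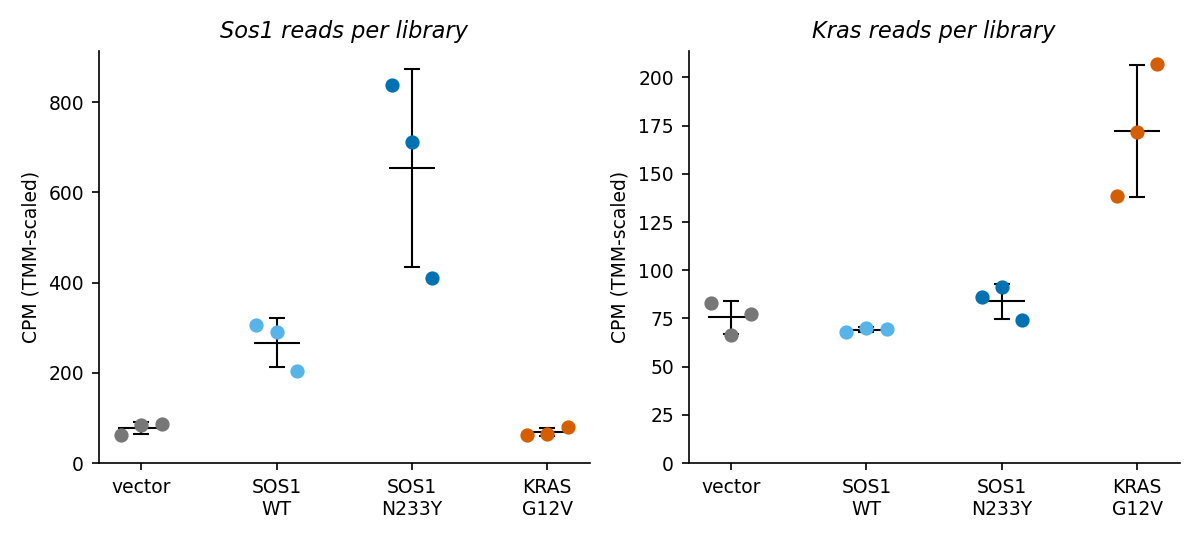
Normalised read counts (CPM) of Sos1 (left) and Kras (right) in each of the 12 libraries, with 1 point per library and the mean and SD of each group in black. Sos1 stood at 205 CPM or more in each of the 6 SOS1 libraries and was highest in SOS1 N233Y, and Kras was highest in KRAS G12V.

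Over all tested genes, SOS1 N233Y lay on average closest to KRAS G12V and SOS1 WT to vector. The first principal component held 50.4% of the variance and placed vector libraries at -42.4 to -32.4, SOS1 WT at -26.6 to -12, SOS1 N233Y at 20.1 to 24.2 and KRAS G12V at 28.7 to 39.2. Along the second, with 16.3%, both SOS1 groups lay below 0 (-23.7 to -7.05 and -22.0 to -15.0), and vector (9.61 to 21.6) and KRAS G12V (15.3 to 19.5) above it. The mean root mean square difference in log2 CPM was 0.520 between SOS1 N233Y and KRAS G12V and between SOS1 WT and vector. Within these groups, in order, it was 0.386, 0.387, 0.447 and 0.417, so the pairs need not be equally close. It was 0.758 and 0.798 from vector to SOS1 N233Y and KRAS G12V and 0.600 between the SOS1 groups. With all 4 groups tested together, edgeR called 3665 genes (37.4%).

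**Figure D2:**
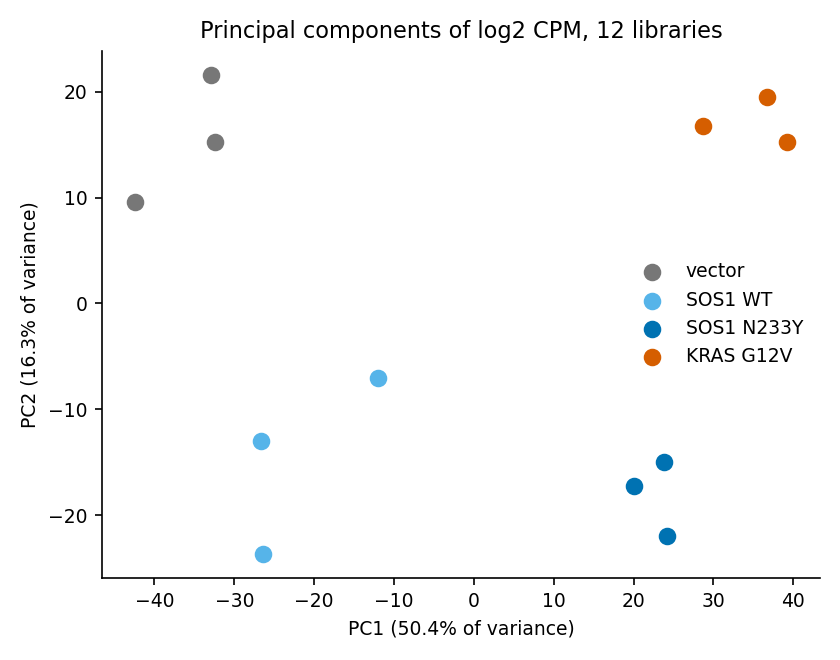
Principal components 1 and 2 of the log2 CPM of 9792 genes, with 1 point per library coloured by group. SOS1 N233Y and KRAS G12V libraries lie at 20.1 and above along the first component, and vector and SOS1 WT libraries at -12 and below.

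KRAS G12V cells were first compared with vector cells. Il33, a cytokine of the interleukin-1 family, had no count in the vector libraries and reached 73.4 ± 20.8 CPM, at least 72.7-fold higher (edgeR adjusted p = 2.47e-07). Lgi2, Itga2 (a collagen-binding integrin subunit) and Add2 (beta adducin) likewise had no count in vector. They were higher by at least 30.2-fold, 16.9-fold and 12.5-fold (edgeR adjusted p = 1.37e-07, 7.98e-07 and 0.00148). Sema7a, a membrane-anchored semaphorin, rose from 1.78 ± 1.48 to 349 ± 126 CPM (7.63, SE 0.71, edgeR adjusted p = 3.59e-05, or 8.43 without vector 2). The pooled-count ratios of the adhesion receptor gene Ceacam1, the Rho GTPase-activating protein gene Arhgap6 and Plxdc1 were 236 (interval 42.0 to 9336), 122 (interval 21.6 to 4857) and 116 (interval 20.4 to 4595). Each was higher in KRAS G12V (edgeR adjusted p = 6.23e-12, 4.68e-10 and 5.43e-10). With single libraries left out, these values were 46.6 to 46.7 for Il33, 19.4 for Lgi2 and 10.9 for Itga2 without vector 1 or vector 3, and 7.12 to 8.05 for Add2 without vector 1, vector 3 or KRAS G12V 2. They were 50.4 to 152 for Ceacam1 without vector 1 or vector 3, and 29.2 to 78.6 for Arhgap6 and 27.6 to 74.4 for Plxdc1 without vector 1, vector 2 or vector 3. In the other direction, the complement protease gene C1s1, the cytochrome P450 gene Cyp1b1, the proteoglycan gene Ogn and the integrin subunit gene Itga11 had no count in KRAS G12V libraries. They stood at 29.1 ± 8.49, 27.2 ± 11.1, 15.2 ± 7.10 and 12.1 ± 5.70 CPM in vector. They were thus at least 38.9-fold, 37.1-fold, 19.9-fold and 15.8-fold lower (edgeR adjusted p = 1.67e-05, 1.97e-07, 2.45e-06 and 1.86e-04). C1s1 has a near-identical neighbour gene, so its level is uncertain where reads matched both. The ratios of vector to KRAS G12V counts were 368 (interval 125 to 1786) for the matrix gene Svep1, 185 (interval 62.8 to 899) for the pentraxin gene Ptx3 and 181 (interval 31.9 to 7187) for adrenomedullin, Adm. Their edgeR adjusted p were 1.27e-06, 3.92e-14 and 7.20e-06. These values became 21.5 for C1s1, 20.5 for Cyp1b1, 11 for Ogn, 8.77 for Itga11, 203.4 for Svep1 and 33.3 for Adm without KRAS G12V 3. The chemokine gene Cxcl12 fell from 151 ± 52.5 to 1.36 ± 1.90 CPM (-6.81, SE 0.79, edgeR adjusted p = 1.44e-04, or -8.40 without KRAS G12V 1). In all, edgeR called 2619 genes, 1268 higher and 1351 lower, of which 388 and 593 differed over 2-fold.

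Targets and feedback regulators of the ERK pathway were mostly higher in KRAS G12V cells. Of the ERK pathway output list, 8 of 10 tested members were higher and 1 lower (8 and 2 adjusted over the list alone). The median log2 fold change was 1.03 (camera adjusted p = 9.19e-05, adjusted p = 0.0776 with an estimated correlation). The ephrin receptor gene Epha4 was the member that was lower (-4.36, SE 0.46, edgeR adjusted p = 3.41e-09). The ERK phosphatase gene Dusp4 rose by 2.22 (SE 0.24, edgeR adjusted p = 2.53e-05), Phlda1 by 1.71 (SE 0.23, edgeR adjusted p = 6.13e-07) and cyclin D1, Ccnd1, by 1.64 (SE 0.22, edgeR adjusted p = 1.80e-04). Of the ERK feedback and delayed early genes, 12 of 16 tested members were higher and 1 lower (12 and 1 adjusted over the list alone) (camera adjusted p = 3.55e-07, adjusted p = 0.0666 with an estimated correlation). Spred3 (1.57, SE 0.29, edgeR adjusted p = 7.15e-05) and Spred1 (1.45, SE 0.14, edgeR adjusted p = 6.59e-10), of a family that restrains RAS signalling, rose most. Among EGF receptor ligands and growth factors, 7 of 12 tested members were higher and 3 lower (8 and 3 adjusted over the list alone). The list as a whole did not pass (camera adjusted p = 0.120). The ligand genes Btc, Areg and Ereg rose, Ereg from 25.3 ± 7.13 to 171 ± 24.1 CPM. Their log2 fold changes were 3.53 (SE 0.58, edgeR adjusted p = 1.01e-05), 2.76 (SE 0.62, edgeR adjusted p = 5.87e-04) and 2.73 (SE 0.19, edgeR adjusted p = 6.18e-12). Fgf7 fell (-2.52, SE 0.27, edgeR adjusted p = 6.69e-07). Growth factor receptors went the other way: 0 of 11 tested members were higher and 6 lower (0 and 9 adjusted over the list alone) (camera adjusted p = 5.40e-05, adjusted p = 0.0666 with an estimated correlation). Pdgfrb (-1.55, SE 0.15, edgeR adjusted p = 2.67e-08) and Fgfr2 (-1.34, SE 0.17, edgeR adjusted p = 1.65e-07) fell most. Immediate early genes were split, 3 higher and 4 lower of 15 (3 and 5 adjusted over the list alone) (camera adjusted p = 0.661). Dusp1 (-2.65, SE 0.34, edgeR adjusted p = 1.95e-07) and Egr2 (-1.91, SE 0.37, edgeR adjusted p = 1.68e-04) were lower and Egr3 higher (1.88, SE 0.24, edgeR adjusted p = 2.38e-07). Nr4a1 was called lower (-2.50, SE 0.57, edgeR adjusted p = 0.0108) but not when 1 library was left out (adjusted p = 0.0541 without KRAS G12V 3). For RAS pathway components the counts were 3 higher and 1 lower of 17 (3 and 1 adjusted over the list alone), with a median of -0.16 against a mean of 0.02 (camera adjusted p = 0.794).

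Matrix and mechanical-response genes fell widely in KRAS G12V cells. Of the fibroblast extracellular matrix list, 1 of 27 tested members was higher and 21 lower (3 and 21 adjusted over the list alone). The median was -1.99 (camera adjusted p = 1.22e-36, adjusted p = 0.0666 with an estimated correlation). Beside Ogn, collagen XII, Col12a1, fell from 159.8 ± 24.8 to 3.45 ± 0.886 CPM (-5.50, SE 0.28, edgeR adjusted p = 1.11e-14) and periostin, Postn, fell as well (-5.18, SE 0.30, edgeR adjusted p = 6.34e-11). Matrix Gla protein, Mgp, fell from 76.0 ± 12.1 to 2.13 ± 1.99 CPM (-5.22, SE 0.34, edgeR adjusted p = 3.22e-13, or -6.11 without KRAS G12V 2). Of the YAP-TEAD targets, 0 of 14 tested members were higher and 11 lower (0 and 11 adjusted over the list alone) (median -2.61; camera adjusted p = 1.47e-13, adjusted p = 0.0666 with an estimated correlation). The matricellular gene Ccn2 fell from 218 ± 68.8 to 4.68 ± 3.63 CPM (-5.31, SE 0.33, edgeR adjusted p = 1.29e-09, or -6.27 without KRAS G12V 3). Ccn1 fell too (-3.16, SE 0.50, edgeR adjusted p = 0.00155). Of the TGF-beta response genes, 2 of 15 tested members were higher and 9 lower (2 and 9 adjusted over the list alone) (camera adjusted p = 1.01e-04, adjusted p = 0.110 with an estimated correlation). The latent TGF-beta binding protein gene Ltbp2 was among them (-5.06, SE 0.34, edgeR adjusted p = 6.90e-08). The inhibitory Smad6 was lower (-4.59, SE 0.48, edgeR adjusted p = 4.45e-07, or -5.24 without KRAS G12V 1), as was Id2 (-2.74, SE 0.25, edgeR adjusted p = 1.11e-08). Tgfbi was higher (2.03, SE 0.21, edgeR adjusted p = 4.81e-09). Contractile genes showed 1 higher and 7 lower of 14 (1 and 8 adjusted over the list alone) (camera adjusted p = 0.00681, adjusted p = 0.495 with an estimated correlation; lost at camera adjusted p = 0.0531 without vector 1). Smooth muscle actin, Acta2, fell from 673 ± 266 to 57.1 ± 7.07 CPM (-3.54, SE 0.45, edgeR adjusted p = 3.63e-04). Matrix proteases and inhibitors did not pass as a list, with 4 higher and 7 lower of 16 (5 and 9 adjusted over the list alone) (camera adjusted p = 0.0892). The aggrecanase gene Adamts5 (-5.37, SE 0.62, edgeR adjusted p = 1.92e-04) and the inhibitor gene Timp3 (-2.46, SE 0.19, edgeR adjusted p = 2.17e-08) fell and cathepsin L, Ctsl, rose (1.93, SE 0.14, edgeR adjusted p = 1.55e-09). Integrins and cell adhesion genes were split as well, 5 higher and 9 lower of 17 (5 and 9 adjusted over the list alone) (camera adjusted p = 0.112). Of cytokines and chemokines, the counts were 3 higher and 3 lower of 8 (4 and 3 adjusted over the list alone). The directions of the median (0.80) and of the test (lower, camera adjusted p = 0.687) differed.

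Most tested cholesterol and ATF4 response genes were lower in KRAS G12V, and cell cycle lists did not pass. Of cholesterol synthesis and uptake genes, 0 of 20 tested members were higher and 12 lower (0 and 16 adjusted over the list alone) (median -0.67; camera adjusted p = 3.59e-05, adjusted p = 0.495 with an estimated correlation). Pmvk (-1.32, SE 0.23, edgeR adjusted p = 4.14e-05) and mevalonate kinase, Mvk (-1.31, SE 0.16, edgeR adjusted p = 7.30e-08), fell most. Of the ATF4 and unfolded protein response genes, 0 of 21 tested members were higher and 14 lower (0 and 15 adjusted over the list alone) (camera adjusted p = 0.00103, adjusted p = 0.406 with an estimated correlation). Chac1 fell most (-1.31, SE 0.30, edgeR adjusted p = 9.32e-04). Trib3 was called lower too (-1.16, SE 0.32, edgeR adjusted p = 0.00634), with its call lost in 1 case (adjusted p = 0.0896 without KRAS G12V 3). MYC targets and ribosome biogenesis genes showed 7 higher and 0 lower of 27 (8 and 0 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.0279, adjusted p = 0.665 with an estimated correlation; lost at camera adjusted p = 0.0632 to 0.186 without vector 2 or KRAS G12V 2). DNA replication genes had 4 higher and 1 lower of 22 (4 and 0 adjusted over the list alone) (camera adjusted p = 0.524). Mitosis genes had 2 higher and 3 lower of 20 (2 and 3 adjusted over the list alone) (camera adjusted p = 0.482). The p53 targets had 2 higher and 5 lower of 13 (2 and 5 adjusted over the list alone) (camera adjusted p = 0.320). Glycolysis genes had 5 higher and 3 lower of 18 (5 and 4 adjusted over the list alone) (camera adjusted p = 0.468). Fatty acid synthesis genes had 1 higher and 6 lower of 11 (1 and 6 adjusted over the list alone) (camera adjusted p = 0.0957). The NRF2 targets had 5 higher and 4 lower of 16 (5 and 4 adjusted over the list alone) (camera adjusted p = 0.661). EMT regulators had 5 higher and 3 lower of 11 (5 and 3 adjusted over the list alone) (camera adjusted p = 0.464). None of these lists passed. The median and mean of glycolysis (0.12 and -0.01), NRF2 targets (0.02 and -0.07) and EMT regulators (-0.04 and 0.10) differed in sign. Interferon-stimulated genes had 0 higher and 3 lower of 5 (0 and 4 adjusted over the list alone) (camera adjusted p = 0.118). Mitochondrially encoded genes had 0 higher and 1 lower of 7 (0 and 0 adjusted over the list alone) (camera adjusted p = 0.370). Cytosolic ribosomal protein genes had 6 higher and 0 lower of 30 (6 and 0 adjusted over the list alone) (camera adjusted p = 0.112). Vimentin, Vim (5226 ± 491 to 9383 ± 332 CPM; 0.84, SE 0.09, edgeR adjusted p = 4.63e-09), rose. Markers of other cell types were mostly below the count filter. No skeletal muscle or epithelial marker was tested, and 2 adipocyte, 2 bone and cartilage, 1 endothelial and 1 macrophage marker were. Of these, Lpl was lower in KRAS G12V (-3.58, SE 0.33, edgeR adjusted p = 4.62e-10) and Sox9 higher (1.11, SE 0.10, edgeR adjusted p = 2.71e-10). The endothelial marker Flt1 was called higher (0.77, SE 0.27, edgeR adjusted p = 0.0307), but its call was lost in 5 cases (adjusted p = 0.0702 to 0.127 without vector 1, vector 3, KRAS G12V 1 or KRAS G12V 2, and 0.0973 with DESeq2). The macrophage marker Cd14 was called higher too (1.01, SE 0.39, edgeR adjusted p = 0.0498), with its call lost without 4 single libraries and with DESeq2 (adjusted p = 0.0926 to 0.198 without vector 1, vector 2, KRAS G12V 1 or KRAS G12V 3, and 0.198 with DESeq2).

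SOS1 N233Y cells were compared with vector cells, and several of the most changed genes were those of the KRAS G12V comparison. Il33 reached 143 ± 44.1 CPM from no count in vector, at least 131-fold higher (edgeR adjusted p = 1.61e-08). Add2 and Lgi2 rose at least 23.5-fold and 20.8-fold (edgeR adjusted p = 1.21e-04 and 1.89e-06). The ratios of SOS1 N233Y to vector counts were 316 (interval 56.4 to 12502) for Plxdc1, 159 (interval 28.3 to 6314) for Arhgap6 and 139 (interval 24.6 to 5503) for the neuronal pentraxin gene Nptx1. Their edgeR adjusted p were 5.60e-14, 3.26e-11 and 6.37e-05. Leaving out libraries gave 83.7 to 84.0 for Il33, 15.1 for Add2 and 13.3 to 13.4 for Lgi2 without vector 1 or vector 3, 75.3 to 203.2 for Plxdc1 and 38.0 to 102 for Arhgap6 without vector 1, vector 2 or vector 3, and 29.7 to 89.2 for Nptx1 without vector 1 or vector 3. Sema7a rose to 329 ± 97.7 CPM (7.52, SE 0.72, edgeR adjusted p = 4.86e-05, or 8.30 without vector 2). The myelin protein gene Plp1 rose from 1.48 ± 1.81 to 218 ± 60.8 CPM (7.26, SE 0.58, edgeR adjusted p = 1.02e-06, or 6.68 without vector 1 and 8.62 without vector 2). Cyp1b1, Rab3c (a RAB GTPase of vesicle release), Ogn and the calcium channel gene Cacna1g had no count in SOS1 N233Y libraries. They were at least 42.6-fold, 36.3-fold, 22.8-fold and 20.8-fold lower (edgeR adjusted p = 1.54e-07, 1.95e-08, 1.60e-06 and 1.11e-04). The ratios of vector to SOS1 N233Y counts were 166 (interval 45.4 to 1379) for the TEAD cofactor gene Vgll3 and 143 (interval 39.1 to 1192) for insulin-like growth factor 2, Igf2 (edgeR adjusted p = 1.31e-10 and 2.52e-06). Leaving out libraries here gave 16.4 for Cyp1b1, 14 for Rab3c, 8.79 for Ogn and 8.0 for Cacna1g without SOS1 N233Y 3, and 257 for Vgll3 and 222 for Igf2 without SOS1 N233Y 2. Svep1 fell from 274 ± 57.3 to 3.04 ± 2.35 CPM (-6.56, SE 0.50, edgeR adjusted p = 1.98e-06) and Ltbp2 from 310.1 ± 113 to 3.73 ± 2.23 (-6.24, SE 0.39, edgeR adjusted p = 3.67e-08). In all, edgeR called 2201 genes, 1136 higher and 1065 lower, of which 446 and 380 differed over 2-fold.

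**Figure D3:**
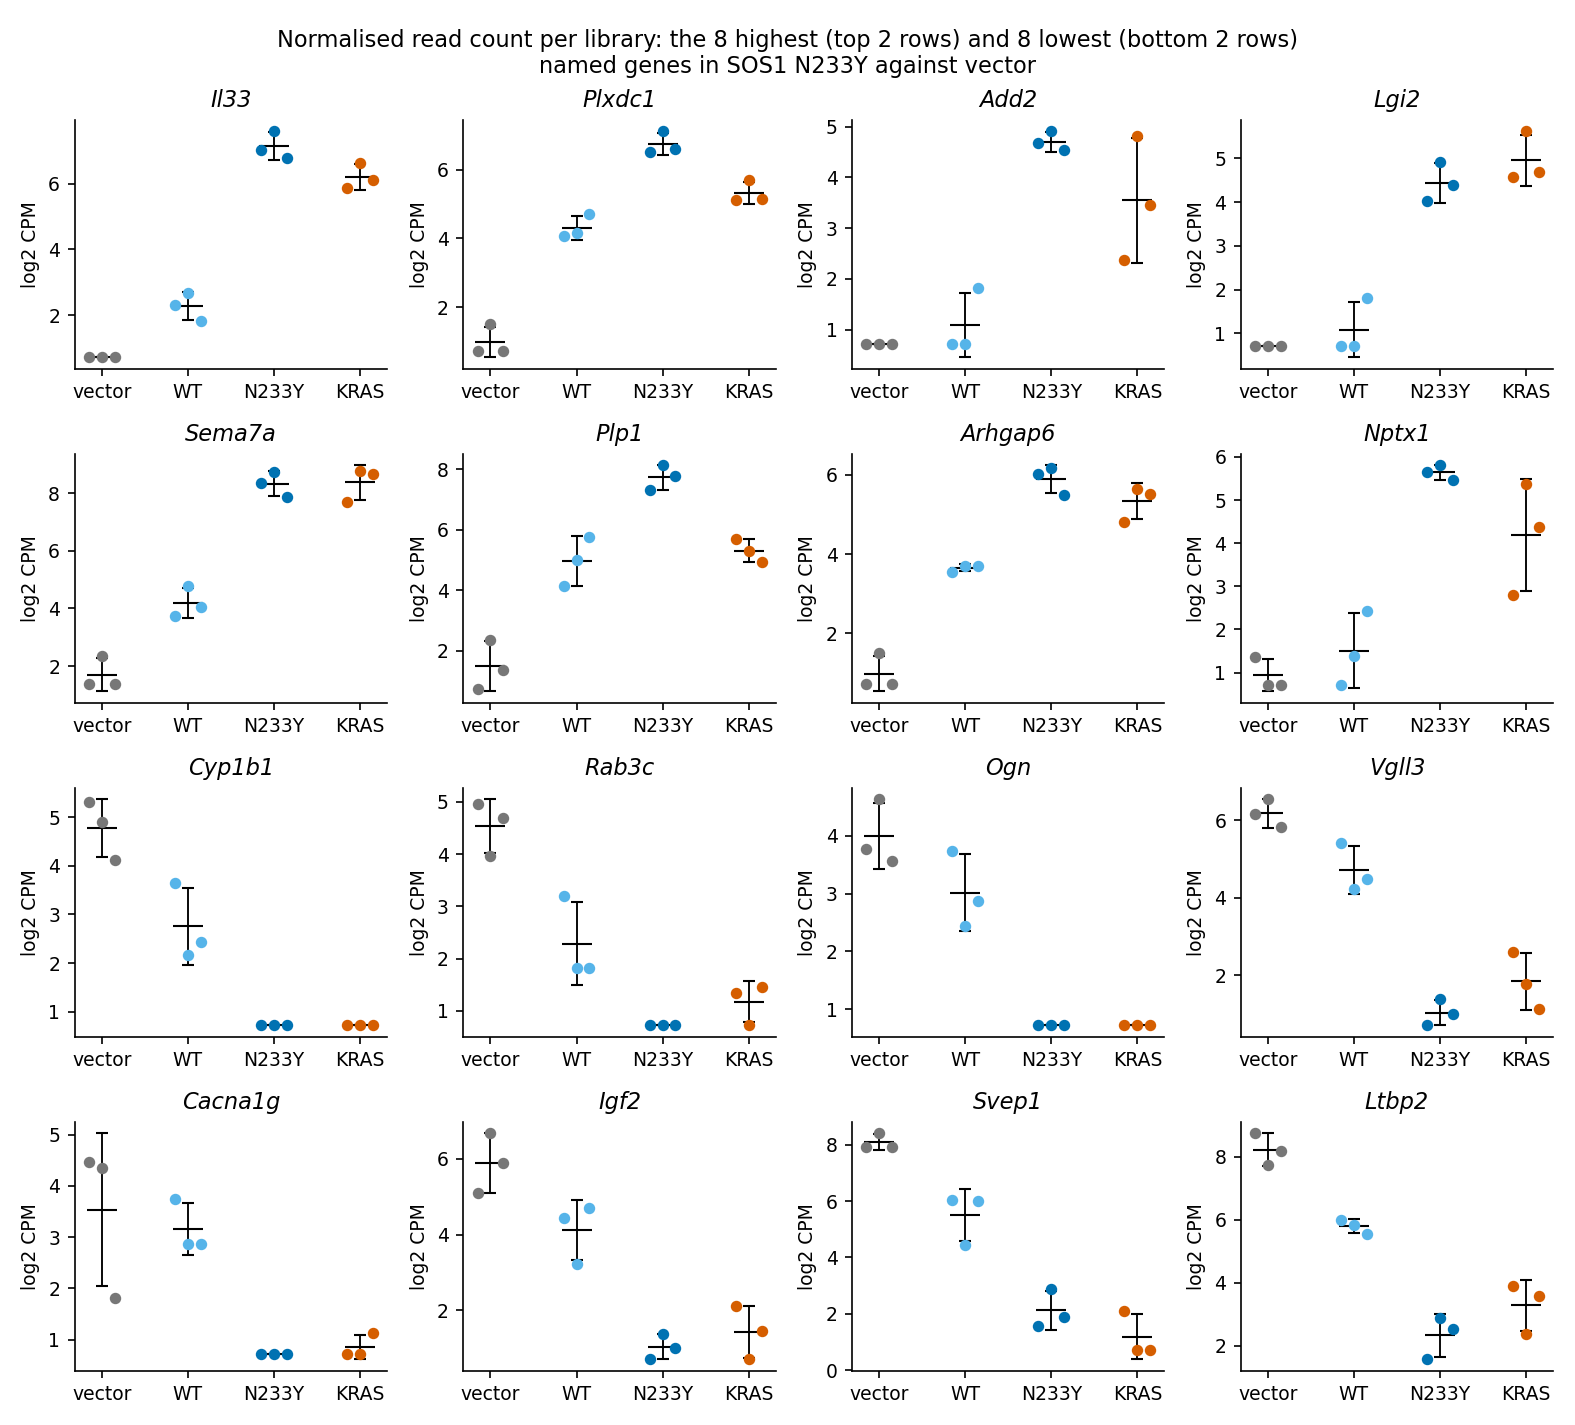
Normalised read count (log2 CPM, prior count 2) per library for the 16 genes of SOS1 N233Y against vector that the naming rule ranks highest and lowest, with 1 point per library and the mean and SD of each group in black. Il33, at the top left, had no count in vector and stood at 143 ± 44.1 CPM in SOS1 N233Y and 73.4 ± 20.8 CPM in KRAS G12V.

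ERK targets were mostly higher in SOS1 N233Y cells, with Epha4 again lower and immediate early genes split. Of the ERK pathway output list, 8 of 10 tested members were higher and 2 lower (8 and 2 adjusted over the list alone) (median 1.11; camera adjusted p = 7.76e-04, adjusted p = 0.108 with an estimated correlation). Epha4 fell (-4.09, SE 0.43, edgeR adjusted p = 4.13e-09, or -5.80 without SOS1 N233Y 3). Phlda1 (1.66, SE 0.23, edgeR adjusted p = 1.36e-06), Ccnd1 (1.65, SE 0.22, edgeR adjusted p = 1.96e-04) and the ERK phosphatase gene Dusp6 (1.56, SE 0.16, edgeR adjusted p = 1.16e-08) rose. Of the ERK feedback and delayed early genes, 11 of 16 tested members were higher and 1 lower (12 and 1 adjusted over the list alone) (camera adjusted p = 5.96e-06, adjusted p = 0.0666 with an estimated correlation). Spred3 (1.80, SE 0.28, edgeR adjusted p = 6.83e-06) and Spred1 (1.69, SE 0.14, edgeR adjusted p = 3.51e-11) rose most. Immediate early genes showed 3 higher and 6 lower of 15 (3 and 7 adjusted over the list alone) (median -0.42; camera adjusted p = 0.524). EGF receptor ligands and growth factors showed 5 higher and 2 lower of 12 (7 and 2 adjusted over the list alone) (camera adjusted p = 0.125). Btc (3.95, SE 0.55, edgeR adjusted p = 6.92e-07) and Areg (3.12, SE 0.58, edgeR adjusted p = 6.75e-05) were higher. Growth factor receptors showed 1 higher and 4 lower of 11 (1 and 4 adjusted over the list alone) (camera adjusted p = 0.0323, adjusted p = 0.180 with an estimated correlation; lost at camera adjusted p = 0.0586 to 0.0782 without vector 2 or SOS1 N233Y 1). Of the ATF4 and unfolded protein response genes, 0 of 21 tested members were higher and 15 lower (0 and 16 adjusted over the list alone) (camera adjusted p = 2.47e-06, adjusted p = 0.205 with an estimated correlation). MYC targets and ribosome biogenesis genes showed 0 higher and 10 lower of 27 (0 and 14 adjusted over the list alone). Their median was -0.31 (camera adjusted p = 0.00406, adjusted p = 0.593 with an estimated correlation; lost at camera adjusted p = 0.0613 without vector 1). Cholesterol genes showed 1 higher and 3 lower of 20 (1 and 3 adjusted over the list alone) and did not pass (camera adjusted p = 0.220). Of the markers of other cell types, Lpl was lower (-4.44, SE 0.37, edgeR adjusted p = 4.78e-11), and Sox9 (1.11, SE 0.10, edgeR adjusted p = 3.44e-10), Flt1 (0.99, SE 0.26, edgeR adjusted p = 0.00431) and Cd14 (1.57, SE 0.36, edgeR adjusted p = 0.00120) were higher.

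Most tested matrix, YAP-TEAD and TGF-beta response genes were lower in SOS1 N233Y cells too. Of the fibroblast extracellular matrix list, 5 of 27 tested members were higher and 18 lower (6 and 19 adjusted over the list alone) (median -1.22; camera adjusted p = 3.00e-20, adjusted p = 0.0666 with an estimated correlation). Thrombospondin 1, Thbs1, fell from 1072 ± 564 to 21.4 ± 6.51 CPM (-5.64, SE 0.58, edgeR adjusted p = 1.02e-04). Col12a1 (-4.73, SE 0.25, edgeR adjusted p = 1.06e-14) and lysyl oxidase, Lox, fell too (-3.95, SE 0.49, edgeR adjusted p = 3.81e-04). Of the YAP-TEAD targets, 1 of 14 tested members was higher and 12 lower (1 and 12 adjusted over the list alone) (camera adjusted p = 1.52e-15, adjusted p = 0.0666 with an estimated correlation). Ccn2 (-5.78, SE 0.35, edgeR adjusted p = 9.50e-10), Ccn1 (-4.71, SE 0.60, edgeR adjusted p = 4.64e-04) and Ankrd1 (-4.49, SE 0.35, edgeR adjusted p = 9.91e-12) fell most. TGF-beta response genes showed 2 higher and 11 lower of 15 (3 and 12 adjusted over the list alone) (camera adjusted p = 4.27e-05, adjusted p = 0.125 with an estimated correlation). Smad6 (-5.06, SE 0.50, edgeR adjusted p = 2.78e-07) and the plasminogen activator inhibitor gene Serpine1 (-3.40, SE 0.22, edgeR adjusted p = 4.21e-12) were lower and Tgfbi higher (3.17, SE 0.19, edgeR adjusted p = 5.00e-14). Of contractile genes, 0 of 14 tested members were higher and 9 lower (0 and 9 adjusted over the list alone) (camera adjusted p = 3.29e-07, adjusted p = 0.188 with an estimated correlation). Acta2 fell to 25.5 ± 10.8 CPM (-4.97, SE 0.52, edgeR adjusted p = 1.21e-04). Matrix proteases and inhibitors showed 7 higher and 3 lower of 16 (7 and 4 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.0283, adjusted p = 0.495 with an estimated correlation; lost at camera adjusted p = 0.0514 to 0.0758 without vector 1 or SOS1 N233Y 2). The members that moved furthest, Adamts5 (-3.99, SE 0.52, edgeR adjusted p = 4.79e-04) and the plasminogen activator gene Plau (-2.57, SE 0.40, edgeR adjusted p = 1.51e-05), fell. Ctsl reached 3439 ± 418 CPM (2.51, SE 0.14, edgeR adjusted p = 5.22e-11).

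**Figure D4:**
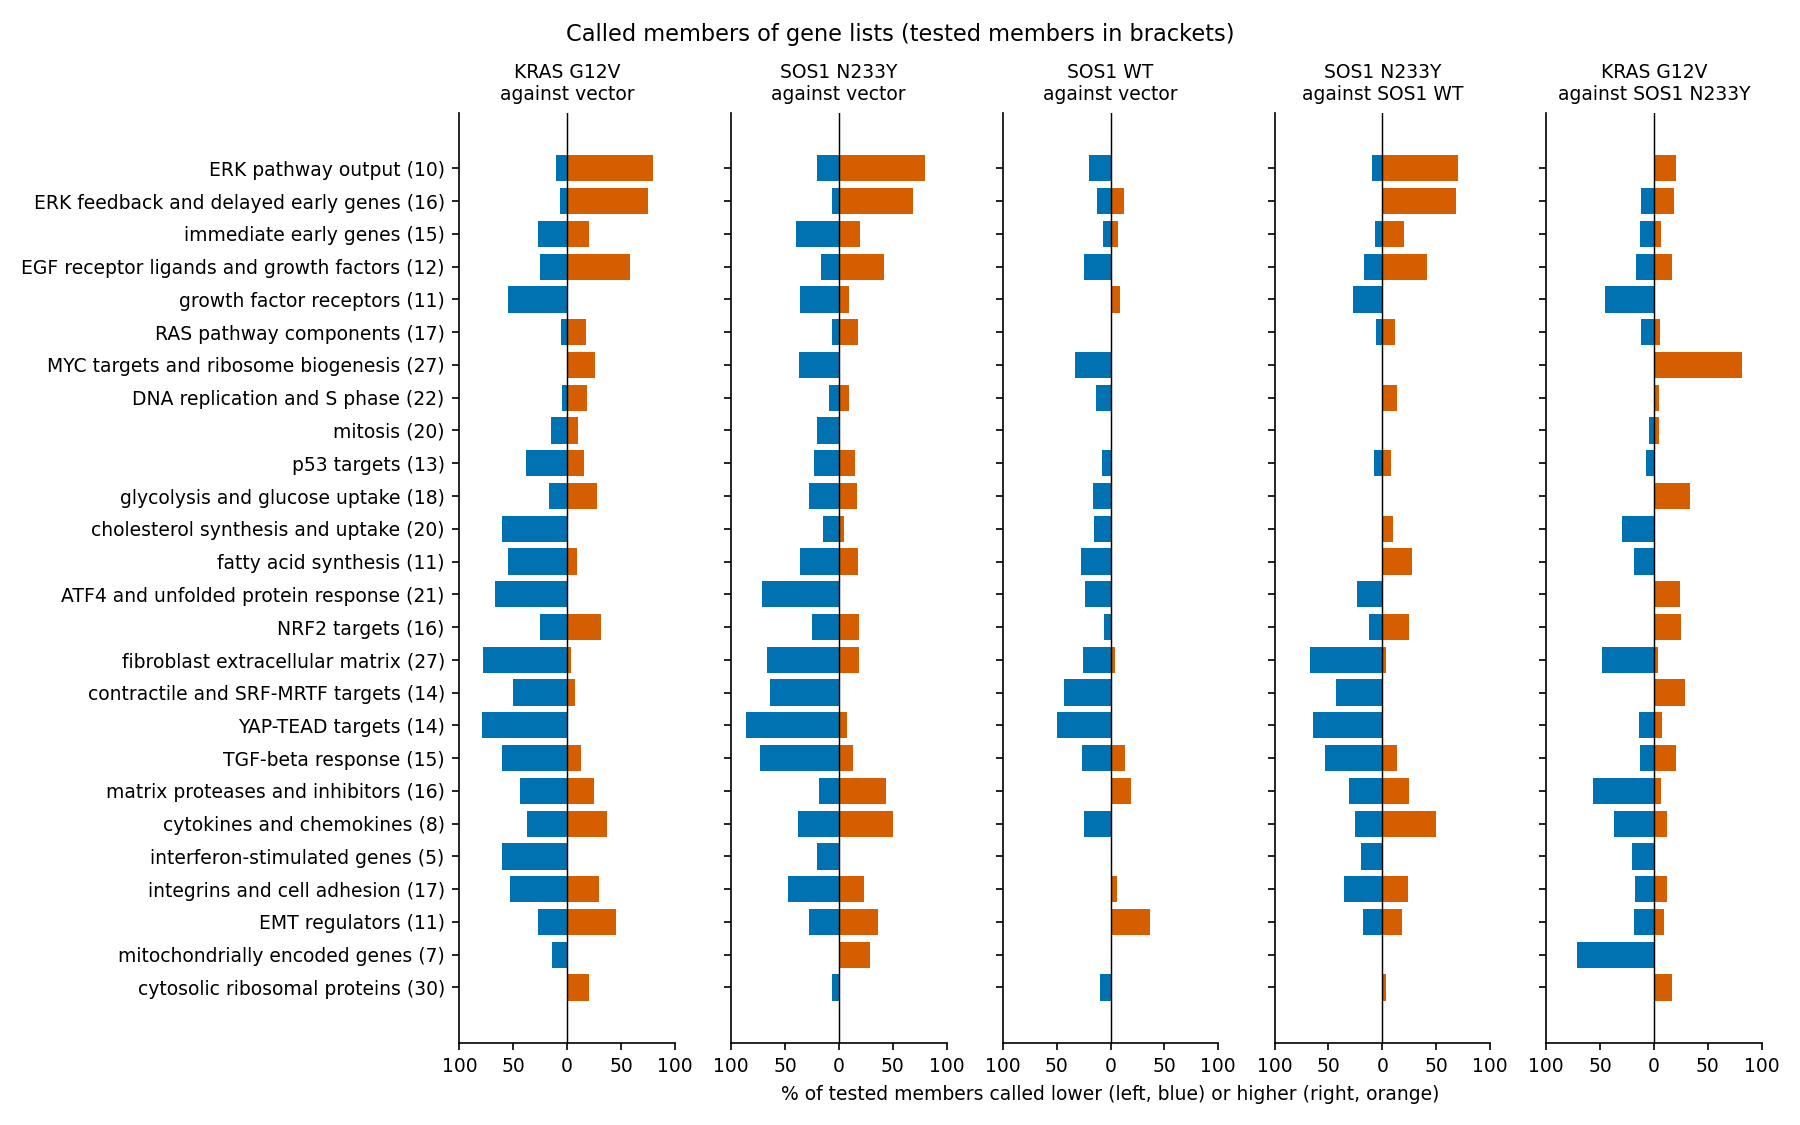
Percentage of the tested members of each of the 26 tested gene lists that edgeR called lower (blue, leftwards) or higher (orange, rightwards) in 5 comparisons, with the number of tested members in brackets. The extracellular matrix list had 21, 18, 7, 18 and 13 of its 27 tested members lower, in the order of the panels.

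SOS1 WT cells were compared with vector cells as the control for the mutation, and fewer genes were called. Against the same vector libraries, 225 of 264 higher genes (85.2%) and 213 of 255 lower genes (83.5%) were called the same way in SOS1 N233Y cells, with 30.6 and 27.7 for independent lists. Simulated groups with those libraries and no changes shared a mean of 0 calls (20 sets), which cannot test this overlap. Part of the excess may come from the shared libraries. The ratio of SOS1 WT to vector counts was 52.1 (interval 8.91 to 2099) for Plxdc1 and 32.5 (interval 5.41 to 1328) for Arhgap6 (edgeR adjusted p = 2.96e-05 and 7.81e-04). Wfdc3, with a ratio of 21.7 (interval 3.47 to 899), was called (edgeR adjusted p = 0.0160), but its call was lost with single libraries left out (adjusted p = 0.0761 to 0.146 without vector 1, vector 3 or SOS1 WT 2). The ratios were 12.4 to 33.5 for Plxdc1 and 7.76 to 20.9 for Arhgap6 without vector 1, vector 2 or vector 3, and 5.17 to 14 for Wfdc3 without vector 1, vector 2, vector 3 or SOS1 WT 2. Plp1 rose to 33.0 ± 18.5 CPM (4.35, SE 0.90, edgeR adjusted p = 0.0145), a call that was also lost in some cases (adjusted p = 0.0512 to 0.0720 without vector 1, vector 3 or SOS1 WT 2). Its log2 fold change ran up to 5.70 without vector 2 and down to 3.76 without vector 1. Nrep rose (3.09, SE 0.71, edgeR adjusted p = 0.00539, or 4.31 without vector 1 and 2.50 without vector 3). The metalloprotease gene Adam12 fell from 39.9 ± 12.2 to 4.72 ± 2.83 CPM (-2.89, SE 0.41, edgeR adjusted p = 2.48e-05). Ptchd4 (-2.84, SE 0.62, edgeR adjusted p = 0.00366), Thbs1 (-2.82, SE 0.47, edgeR adjusted p = 0.0110), Svep1 (-2.52, SE 0.33, edgeR adjusted p = 0.00147) and Ltbp2 (-2.49, SE 0.27, edgeR adjusted p = 1.27e-04) fell as well. In all, edgeR called 520 genes, 265 higher and 255 lower, of which 85 and 61 differed over 2-fold. The count was 275 without vector 1 and 333 without SOS1 WT 3, the shallowest library.

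In SOS1 WT cells the lists that passed included matrix and mechanical-response genes, and the ERK lists did not pass. Of the ERK pathway output list, 0 of 10 tested members were higher and 2 lower (3 and 2 adjusted over the list alone) (camera adjusted p = 0.482). The called members were Epha4 (-1.83, SE 0.35, edgeR adjusted p = 9.53e-04) and Epha2 (-1.01, SE 0.20, edgeR adjusted p = 0.00209). ERK feedback genes showed 2 higher and 2 lower of 16 (2 and 2 adjusted over the list alone) (camera adjusted p = 0.215). Plaur, their largest change, was called lower (-1.09, SE 0.27, edgeR adjusted p = 0.0171), but not in 3 cases (adjusted p = 0.0633 to 0.187 without vector 1, SOS1 WT 1 or SOS1 WT 2). Spred1 was higher (0.80, SE 0.15, edgeR adjusted p = 6.52e-04). Of the YAP-TEAD targets, 0 of 14 tested members were higher and 7 lower (1 and 8 adjusted over the list alone) (camera adjusted p = 7.83e-09, adjusted p = 0.0694 with an estimated correlation). Ccn1 was called lower (-2.26, SE 0.49, edgeR adjusted p = 0.0345) but lost its call with several libraries left out (adjusted p = 0.0526 to 0.104 without vector 1, vector 2, vector 3, SOS1 WT 2 or SOS1 WT 3; -2.93 without SOS1 WT 1). Ankrd1 (-1.68, SE 0.27, edgeR adjusted p = 1.07e-04) and Ccn2 (-1.46, SE 0.23, edgeR adjusted p = 7.11e-04) were lower with each library left out as well. Of the fibroblast extracellular matrix list, 1 of 27 tested members was higher and 7 lower (4 and 11 adjusted over the list alone) (camera adjusted p = 1.84e-06, adjusted p = 0.306 with an estimated correlation). Of contractile genes, 0 of 14 tested members were higher and 6 lower (0 and 10 adjusted over the list alone) (camera adjusted p = 1.69e-07, adjusted p = 0.180 with an estimated correlation). Acta2 was lower (-1.95, SE 0.41, edgeR adjusted p = 0.0298), though not in 3 cases (adjusted p = 0.0638 to 0.0937 without vector 1, SOS1 WT 2 or SOS1 WT 3). MYC targets and ribosome biogenesis genes showed 0 higher and 9 lower of 27 (0 and 20 adjusted over the list alone) (camera adjusted p = 2.39e-11, adjusted p = 0.20 with an estimated correlation). Rrp12 was called lower (-0.73, SE 0.19, edgeR adjusted p = 0.0244) but not with either of 2 libraries left out (adjusted p = 0.169 to 0.230 without vector 1 or SOS1 WT 1). ATF4 and unfolded protein response genes showed 0 higher and 5 lower of 21 (0 and 5 adjusted over the list alone) (camera adjusted p = 5.31e-06, adjusted p = 0.218 with an estimated correlation).

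SOS1 N233Y cells were set against SOS1 WT cells, and most tested ERK target and matrix genes separated them. SOS1 N233Y cells also had more Sos1 reads, as given above, so this comparison differs in Sos1 RNA as well as in sequence. Itga2, with no count in SOS1 WT, was at least 4.54-fold higher (edgeR adjusted p = 0.00383). Il33 stood at 143 ± 44.1 against 3.33 ± 1.43 CPM (5.23, SE 0.41, edgeR adjusted p = 4.36e-07). The ratios of SOS1 N233Y to SOS1 WT counts were 65.1 (interval 11.4 to 2594) for Add2, 57.4 (interval 10.1 to 2290) for Lgi2, 42.6 (interval 14.4 to 208) for Nptx1 and 20.7 (interval 5.52 to 174) for Klra4. Their edgeR adjusted p were 6.46e-04, 2.46e-05, 3.42e-04 and 4.58e-05. Klra4 belongs to a family of closely similar receptor genes, so its reads are uncertain. Shroom2 and Gch1 had ratios of 29.0 (interval 4.97 to 1168) and 23.1 (interval 3.91 to 935) (edgeR adjusted p = 0.00498 and 0.0138). Shroom2 lost its call in 1 case (adjusted p = 0.0598 without SOS1 WT 1) and Gch1 in 2 (adjusted p = 0.0600 to 0.116 without SOS1 WT 1 or SOS1 WT 2). With libraries left out, the values were 2.59 to 2.82 for Itga2 without SOS1 WT 1 or SOS1 WT 2, 17.5 to 40.4 for Add2 and 15.5 to 35.7 for Lgi2 without SOS1 WT 1, SOS1 WT 2 or SOS1 WT 3, and 24.3 to 103 for Nptx1 and 11.8 to 33.5 for Klra4 without SOS1 WT 1 or SOS1 WT 3. They were 6.0 to 16.5 for Shroom2 without SOS1 WT 1 or SOS1 WT 2, and 6.22 to 38.4 for Gch1 without SOS1 WT 1, SOS1 WT 2, SOS1 WT 3 or SOS1 N233Y 3. Cacna1g, Ogn and Cyp1b1 had no count in SOS1 N233Y libraries. They were at least 13.0-fold, 11.8-fold and 10.1-fold lower (edgeR adjusted p = 0.00267, 3.53e-04 and 0.00168). Rab3c was at least 6.76-fold lower (edgeR adjusted p = 0.00361, and adjusted p = 0.0545 to 0.126 without SOS1 WT 1 or SOS1 N233Y 3). The ratios of SOS1 WT to SOS1 N233Y counts were 65.9 (interval 17.6 to 554) for Vgll3, 38.0 (interval 9.93 to 324) for Igf2 and 27.6 (interval 8.91 to 138) for Cd24a (edgeR adjusted p = 7.38e-07, 0.00275 and 0.0214). Igf2 lost its call in 1 case (adjusted p = 0.0604 without SOS1 N233Y 3) and Cd24a in 4 (adjusted p = 0.0535 to 0.176 without SOS1 WT 1, SOS1 WT 3, SOS1 N233Y 2 or SOS1 N233Y 3). These values became 4.99 for Cacna1g without SOS1 N233Y 3, 4.55 to 6.91 for Ogn, 3.90 to 4.94 for Cyp1b1 and 2.60 to 2.96 for Rab3c without SOS1 WT 1 or SOS1 N233Y 3, and 43.0 to 102 for Vgll3 without SOS1 WT 1 or SOS1 N233Y 2. They became 59.0 for Igf2 without SOS1 N233Y 2, and 11.9 to 69.5 for Cd24a without SOS1 WT 1, SOS1 N233Y 1 or SOS1 N233Y 3. Ccn2 stood at 3.66 ± 0.703 against 79.3 ± 17.7 CPM (-4.32, SE 0.41, edgeR adjusted p = 1.25e-06). In all, edgeR called 1176 genes, 626 higher and 550 lower, of which 193 and 247 differed over 2-fold, and the count was 669 without SOS1 WT 1.

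ERK targets were mostly higher and matrix genes mostly lower in SOS1 N233Y than in SOS1 WT cells. Of the ERK pathway output list, 7 of 10 tested members were higher and 1 lower (7 and 2 adjusted over the list alone) (camera adjusted p = 4.91e-05, adjusted p = 0.0666 with an estimated correlation). Epha4 was lower (-2.26, SE 0.56, edgeR adjusted p = 0.00430; -3.97 without SOS1 N233Y 3) but not in 1 case (adjusted p = 0.113 without SOS1 WT 1). Ccnd1 was higher, at 889.8 ± 51.9 against 336 ± 70.3 CPM (1.40, SE 0.22, edgeR adjusted p = 0.00144). Dusp4 was higher too (1.10, SE 0.24, edgeR adjusted p = 0.0101), a call lost in 1 case (adjusted p = 0.0504 without SOS1 WT 3), as was Dusp6 (1.01, SE 0.15, edgeR adjusted p = 2.83e-05). Of the ERK feedback and delayed early genes, 11 of 16 tested members were higher and 0 lower (12 and 1 adjusted over the list alone) (camera adjusted p = 1.89e-07, adjusted p = 0.0666 with an estimated correlation). Of the EGF receptor ligands and growth factors, 5 of 12 tested members were higher and 2 lower (6 and 2 adjusted over the list alone) (camera adjusted p = 7.76e-04, adjusted p = 0.152 with an estimated correlation). Areg had a ratio of 11.6 (interval 3.79 to 58.0) (edgeR adjusted p = 1.55e-04), which was 21.7 for Areg without SOS1 WT 2. Btc (2.21, SE 0.42, edgeR adjusted p = 3.17e-04) and Ereg (2.02, SE 0.20, edgeR adjusted p = 2.86e-08) were higher as well. Cytokines and chemokines showed 4 higher and 2 lower of 8 (5 and 3 adjusted over the list alone) and did not pass (camera adjusted p = 0.107). Of the fibroblast extracellular matrix list, 1 of 27 tested members was higher and 18 lower (2 and 18 adjusted over the list alone) (median -0.99; camera adjusted p = 4.23e-21, adjusted p = 0.0666 with an estimated correlation). Of the YAP-TEAD targets, 0 of 14 tested members were higher and 9 lower (0 and 11 adjusted over the list alone) (camera adjusted p = 2.39e-11, adjusted p = 0.0666 with an estimated correlation). TGF-beta response genes showed 2 higher and 8 lower of 15 (2 and 8 adjusted over the list alone) (camera adjusted p = 0.00134, adjusted p = 0.188 with an estimated correlation). Ltbp2 moved furthest (-3.75, SE 0.51, edgeR adjusted p = 1.95e-04). MYC targets and ribosome biogenesis genes showed 0 higher and 0 lower of 27 (0 and 0 adjusted over the list alone) (camera adjusted p = 0.274), with a median of 0.09.

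KRAS G12V cells were set directly against SOS1 N233Y cells. Among the genes higher in KRAS G12V, cardiac troponin T, Tnnt2, stood at 35.1 ± 19.6 against 8.03 ± 3.39 CPM (2.34, SE 0.44, edgeR adjusted p = 0.00177). Igfbp4 was called higher (2.20, SE 0.48, edgeR adjusted p = 0.00170) but not in 2 cases (adjusted p = 0.0841 without SOS1 N233Y 3 or KRAS G12V 3), with a log2 fold change of 1.52 without SOS1 N233Y 3. Hes1 was called (2.16, SE 0.70, edgeR adjusted p = 0.0276) but not in 5 cases (adjusted p = 0.0761 to 0.141 without SOS1 N233Y 2, SOS1 N233Y 3, KRAS G12V 1 or KRAS G12V 3, and 0.0586 with DESeq2). Angptl4 was called (2.12, SE 0.44, edgeR adjusted p = 0.0150) but not in 2 (adjusted p = 0.0597 to 0.0902 without SOS1 N233Y 2 or SOS1 N233Y 3), and Gprc5a (2.03, SE 0.43, edgeR adjusted p = 0.00604) not in 1 (adjusted p = 0.0754 without SOS1 N233Y 3). Among the genes lower in KRAS G12V, Lrrc17 had a ratio of SOS1 N233Y to KRAS G12V counts of 48.8 (interval 8.41 to 1963) (edgeR adjusted p = 6.79e-05). Bmf had a ratio of 15.7 (interval 2.48 to 654) (edgeR adjusted p = 0.0206, lost at adjusted p = 0.0561 to 0.171 without SOS1 N233Y 3, KRAS G12V 1 or KRAS G12V 3, and 0.0560 with DESeq2). For AW551984 it was 12.2 (interval 3.90 to 61.6) (edgeR adjusted p = 0.00532, lost at adjusted p = 0.0569 without KRAS G12V 3). For C1ra it was 14.8 (interval 2.32 to 619) (edgeR adjusted p = 0.0270, lost at adjusted p = 0.0561 to 0.158 without SOS1 N233Y 2, SOS1 N233Y 3, KRAS G12V 2 or KRAS G12V 3). For H2-T23 it was 11.8 (interval 2.96 to 102) (edgeR adjusted p = 0.00899, lost at adjusted p = 0.0792 to 0.0894 without SOS1 N233Y 2 or KRAS G12V 3). The ratios became 9.01 for Lrrc17 without KRAS G12V 3, 3.79 to 8.68 for Bmf without KRAS G12V 2 or KRAS G12V 3, and 26.5 for AW551984 without KRAS G12V 2. They became 3.57 to 8.20 for C1ra without KRAS G12V 1 or KRAS G12V 3, and 5.67 to 18.1 for H2-T23 without SOS1 N233Y 2, SOS1 N233Y 3, KRAS G12V 1 or KRAS G12V 3. C1ra and H2-T23 belong to families of similar genes. In all, edgeR called 1433 genes, 630 higher and 803 lower, of which 46 and 246 differed over 2-fold. The count was 688 without SOS1 N233Y 3 (the deepest library), 725 without KRAS G12V 3, 945 without SOS1 N233Y 2 and 808 with DESeq2.

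Most MYC target genes were higher in KRAS G12V than in SOS1 N233Y, and some matrix and most protease genes lower. Of the MYC targets and ribosome biogenesis list, 22 of 27 tested members were higher and 0 lower (24 and 0 adjusted over the list alone). The median was 0.52 (camera adjusted p = 6.68e-17, adjusted p = 0.119 with an estimated correlation). Ornithine decarboxylase, Odc1, stood at 214 ± 67.8 against 98.6 ± 14.4 CPM (1.18, SE 0.25, edgeR adjusted p = 0.00905), with its call lost in 2 cases (adjusted p = 0.0526 to 0.0620 without SOS1 N233Y 2 or SOS1 N233Y 3). Cytosolic ribosomal protein genes, many of which have processed copies that can share reads, showed 5 higher and 0 lower of 30 (5 and 0 adjusted over the list alone) (camera adjusted p = 5.46e-05, adjusted p = 0.495 with an estimated correlation). Glycolysis genes showed 6 higher and 0 lower of 18 (7 and 0 adjusted over the list alone) (camera adjusted p = 0.00292, adjusted p = 0.463 with an estimated correlation). Matrix proteases and inhibitors showed 1 higher and 9 lower of 16 (2 and 10 adjusted over the list alone) (camera adjusted p = 2.39e-11, adjusted p = 0.0666 with an estimated correlation). Mmp19 (-2.74, SE 0.28, edgeR adjusted p = 3.44e-07) and Timp3 (-1.83, SE 0.19, edgeR adjusted p = 1.28e-05) were lowest. Of the fibroblast extracellular matrix list, 1 of 27 tested members was higher and 13 lower (1 and 15 adjusted over the list alone) (camera adjusted p = 3.60e-10, adjusted p = 0.180 with an estimated correlation). Lowest were Mgp (-3.18, SE 0.44, edgeR adjusted p = 1.00e-05, or -4.07 without KRAS G12V 2) and Postn (-2.06, SE 0.42, edgeR adjusted p = 0.00236). Growth factor receptors showed 0 higher and 5 lower of 11 (0 and 6 adjusted over the list alone) (camera adjusted p = 0.00406, adjusted p = 0.0999 with an estimated correlation). Cholesterol genes showed 0 higher and 6 lower of 20 (0 and 12 adjusted over the list alone) (camera adjusted p = 9.58e-06, adjusted p = 0.495 with an estimated correlation). Mitochondrially encoded genes showed 0 higher and 5 lower of 7 (0 and 5 adjusted over the list alone) (camera adjusted p = 2.13e-04, adjusted p = 0.400 with an estimated correlation). For the lists by which each group had differed from vector, the ERK pathway output counts were 2 higher and 0 lower of 10 (2 and 0 adjusted over the list alone) (median 0.06; camera adjusted p = 0.306). The YAP-TEAD counts were 1 higher and 2 lower of 14 (2 and 2 adjusted over the list alone) (median 0.07; camera adjusted p = 0.813). Among cytokines and chemokines, with 1 higher and 3 lower of 8 (1 and 4 adjusted over the list alone) (camera adjusted p = 0.225), the called members included Ccl8, Ptgs2 and Il33. Ccl8 was lower (-2.58, SE 0.55, edgeR adjusted p = 0.00142) and Ptgs2 higher (1.79, SE 0.27, edgeR adjusted p = 3.19e-04). Il33 was lower in KRAS G12V than in SOS1 N233Y cells (-0.93, SE 0.22, edgeR adjusted p = 0.00883), a call lost in 1 case (adjusted p = 0.0631 without KRAS G12V 3).

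KRAS G12V cells were also set against SOS1 WT cells, as the reference for the direct comparison, and edgeR called 3039 genes, 1466 higher and 1573 lower. Itga2 was at least 15.6-fold higher (edgeR adjusted p = 2.22e-06). Ceacam1 stood at 75.5 ± 13.8 against 2.53 ± 2.90 CPM (4.87, SE 0.39, edgeR adjusted p = 2.46e-10, or 4.08 without SOS1 WT 1 and 6.81 without SOS1 WT 2). C1s1 and Brinp3 had no count in KRAS G12V and were at least 40.8-fold and 12.8-fold lower (edgeR adjusted p = 2.27e-05 and 7.46e-05). With libraries left out, these bounds were 8.90 to 9.69 for Itga2 without SOS1 WT 1 or SOS1 WT 2, 22.4 to 22.6 for C1s1 without SOS1 WT 1 or KRAS G12V 3, and 7.07 for Brinp3 without KRAS G12V 3. Of the MYC targets and ribosome biogenesis list, 25 of 27 tested members were higher and 0 lower (25 and 0 adjusted over the list alone) (camera adjusted p = 1.11e-10, adjusted p = 0.207 with an estimated correlation). Of the cytosolic ribosomal proteins, 17 of 30 tested members were higher and 0 lower (20 and 0 adjusted over the list alone) (camera adjusted p = 2.80e-05, adjusted p = 0.495 with an estimated correlation). In SOS1 WT against vector that list showed 0 higher and 3 lower of 30 (0 and 3 adjusted over the list alone) (camera adjusted p = 5.85e-05, adjusted p = 0.495 with an estimated correlation). The ERK pathway output list showed 7 higher and 1 lower of 10 (8 and 1 adjusted over the list alone) (camera adjusted p = 2.08e-04, adjusted p = 0.0865 with an estimated correlation). The fibroblast extracellular matrix list showed 1 higher and 20 lower of 27 (2 and 21 adjusted over the list alone) (camera adjusted p = 3.73e-28, adjusted p = 0.0666 with an estimated correlation).

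The likeness of the SOS1 N233Y and KRAS G12V profiles was measured across 9790 genes, leaving out Sos1 and Kras. Log2 fold changes against vector correlated with r = 0.840 across genes, which are not independent replicates. Groups simulated without any change but sharing the same vector libraries gave a mean r of 0.559. The covariance was 0.559 observed and 0.0322 simulated, a difference of 0.527. KRAS G12V and SOS1 WT, which also share the vector libraries, had r = 0.467, below the simulated mean of 0.515, and a covariance of 0.167 against 0.0321 simulated, a difference of 0.135. For SOS1 N233Y and SOS1 WT r was 0.729 against a simulated mean of 0.520, and the covariance 0.241 against 0.0322, a difference of 0.209. Without shared libraries, the log2 fold changes of KRAS G12V against vector and of SOS1 N233Y against SOS1 WT correlated with r = 0.829, with a simulated mean of 0.00215 and a highest simulated value of 0.0486. With genes down to 1 CPM in 3 libraries included, that r was 0.596. The genes higher in KRAS G12V and in SOS1 N233Y against vector shared 759 genes (of 1267 and 1135, with 147 for independent lists). The lower ones shared 710 (of 1351 and 1065, with 147), while 17 genes went opposite ways. Simulated unchanged groups with the same vector libraries shared a mean of 0.05 called genes, both directions together (20 sets), which cannot test this overlap. Part of the excess may come from the shared vector libraries, which are too few to be split into parts of at least 2 libraries. Of the 1267 genes higher in KRAS G12V, 531 were also higher in SOS1 N233Y than in SOS1 WT and 0 lower. Over all 1267 the median log2 fold change was 0.40 (camera adjusted p = 5.16e-67, and adjusted p = 2.39e-04 with an estimated correlation). Of the 1351 lower genes, 481 were also lower and 1 higher. Over all 1351 it was -0.43 (camera adjusted p = 2.93e-54, and adjusted p = 0.00133 with an estimated correlation). On a scale from the vector mean (0%) to the KRAS G12V mean (100%), the SOS1 N233Y libraries lay at 78.9%, 79.3% and 75.7%. The SOS1 WT libraries lay at 15.7%, 35.0% and 18.0%, against a mean of 4.97% for simulated unchanged libraries.

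**Figure D5:**
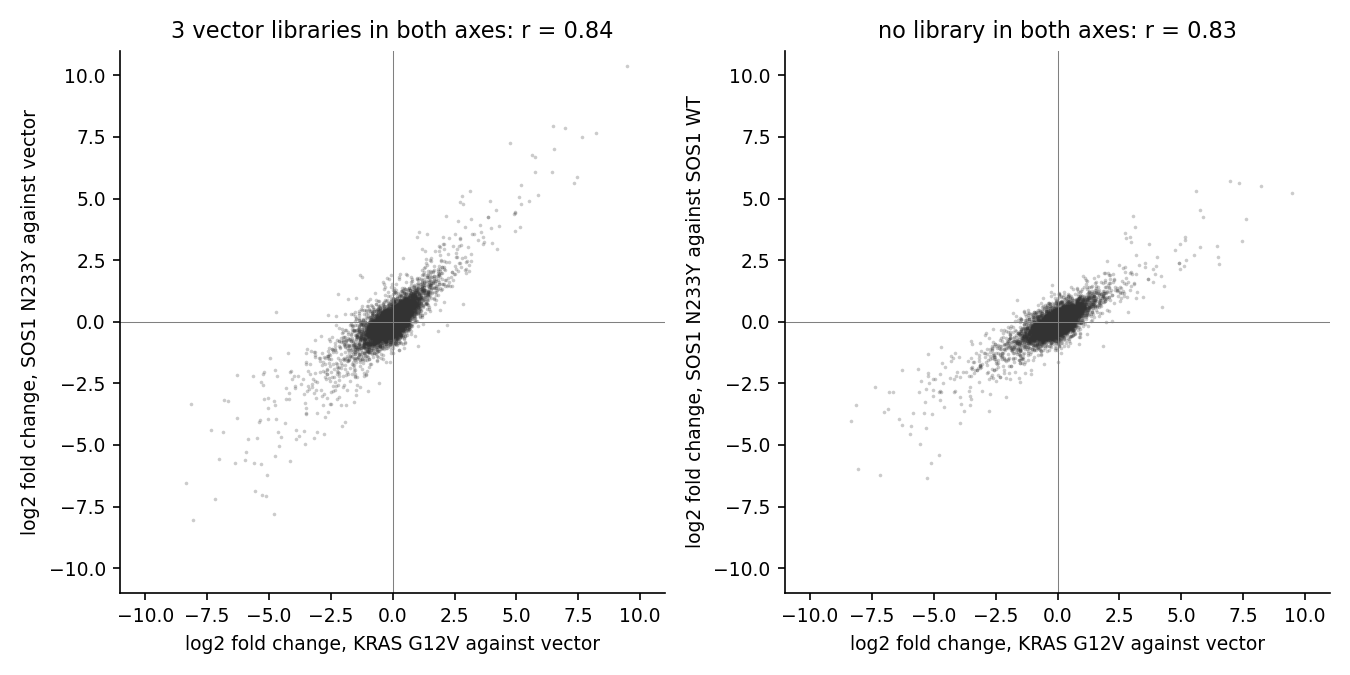
Log2 fold changes of 9790 genes, 1 point per gene, with KRAS G12V against vector on both horizontal axes and SOS1 N233Y against vector (left) or against SOS1 WT (right) on the vertical axes. The left comparison shares the 3 vector libraries between its axes (r = 0.840) and the right shares none (r = 0.829).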

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

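The tests of mixing, of Sos1 dose and of scaling, and the comparison of single libraries after trends were removed, were chosen after the results they bear on were seen, and those of other splits and of trends with gene length, GC content and expression before. Reads aligned to more than 1 place, which enter no comparison, were more frequent in every SOS1 N233Y and KRAS G12V library than in the highest vector library (18.3 per 100 reads counted in genes, or 18.2557 before rounding). The lowest SOS1 N233Y library had 18.3 (18.30336 before rounding) and the lowest KRAS G12V library 19.6. SOS1 WT 2, at 18.4, also lay above the highest vector library and above 2 SOS1 N233Y libraries, and the other SOS1 WT libraries, at 17.8 and 16.8, lay below it. No explanation of these values was tested.

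SOS1 WT libraries lay part of the way from vector to SOS1 N233Y. If SOS1 N233Y cells or RNA were mixed into them, 1 fraction per library would account for higher and lower genes alike. Over 98 genes more than 4-fold higher in SOS1 N233Y, the implied median fraction was 19.1%, 25.2% and 21.5% in the 3 SOS1 WT libraries, and over 131 lower genes 43.5%, 70.7% and 46.5%. The smallest difference was 24.3 percentage points, which argues against a single mixing fraction as the whole cause. A milder response to wild-type SOS1 stays open as an untested hypothesis.

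SOS1 N233Y libraries lay further from vector than SOS1 WT libraries, and they also had more Sos1 reads. From the shift per Sos1 CPM of the SOS1 WT libraries, 2 of the 3 SOS1 N233Y libraries lay inside the predicted range (78.9% in 52.2 to 126% and 79.3% in 43.5 to 105%). SOS1 N233Y 3, at 75.7%, lay above its range of 22.8 to 55%. The dose of Sos1 and the substitution therefore cannot be told apart, because dose differs with the groups and 1 library alone went past the range.

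MYC targets and ribosome biogenesis genes were higher in KRAS G12V than in SOS1 N233Y, a camera call lost with an estimated correlation (adjusted p = 0.119). Scaling moves all genes of a library together and leaves the median of the 27 members relative to that of all tested genes. This value (log2) was 0.22 to 0.40 in KRAS G12V (SD 0.10) and -0.24 to -0.14 in SOS1 N233Y libraries (SD 0.05). This gap of 0.36 argues against scaling as the whole cause. SOS1 WT lay at -0.38 to -0.21 and vector at -0.11 to 0.26, overlapping KRAS G12V and above both SOS1 groups. After trends with gene length, GC content and expression were removed, the gap was 0.34 and the list's median fold change exceeded that of all genes by 0.50 (central 95% of 10000 random lists, which leave out the correlation between genes, -0.17 to 0.16), which argues against those trends as the whole cause. A difference in biology stays open and was not tested further.

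Other splits of the libraries were counted for each comparison. Of the 10 splits of the 6 libraries, 1 gave as many calls as the labels in each comparison, namely the labels themselves. The real counts were 2619, 2201, 520, 1176, 1433 and 3039, and the highest of the other splits gave 0, 0, 1, 0, 1 and 0, with KRAS G12V, SOS1 N233Y and SOS1 WT against vector, then SOS1 N233Y against SOS1 WT and KRAS G12V against SOS1 N233Y and SOS1 WT. With 10 splits no share under 0.05 can be reached. For the test across all 4 groups, 1 of 100 splits gave as many calls (3665, and 1683 at most in the others). This argues against chance there.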

How the results depend on the processing

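Thinning and the fits without the shallowest and deepest libraries were chosen after the data were seen. Leaving out 1 library at a time gave 1967 to 2624 called genes for KRAS G12V against vector, 1714 to 2101 for SOS1 N233Y against vector, 275 to 503 for SOS1 WT against vector, 669 to 1214 for SOS1 N233Y against SOS1 WT, 688 to 1343 for KRAS G12V against SOS1 N233Y and 2034 to 3012 for KRAS G12V against SOS1 WT. The lowest of these were without KRAS G12V 3, SOS1 N233Y 3, vector 1, SOS1 WT 1, SOS1 N233Y 3 and SOS1 WT 1. The correlation of profiles ran from 0.817 to 0.850 with shared vector libraries and from 0.776 to 0.823 without. Tested against a 1.5-fold change, the counts were 857, 732, 40, 287, 89 and 710 in the same order, by the stricter null. DESeq2 called 808 genes for KRAS G12V against SOS1 N233Y, and the cause was not tested. Thinned to the shallowest library, 1210, 1039, 153, 475, 305 and 1227 genes were called, and 1524 for any difference among the 4 groups. Depth thus limits the counts. Without the shallowest and deepest libraries, 273 genes were called for SOS1 WT against vector, 643 for SOS1 N233Y against SOS1 WT and 658 for KRAS G12V against SOS1 N233Y, with fewer samples. The correlation with shared vector libraries was 0.791 with genes down to 1 CPM in 3 libraries, 0.871 over genes that differed among groups and 0.652 by rank (Spearman). Without shared libraries these were 0.596, 0.893 and 0.647. Of 66 called lists, 0 held with an estimated correlation. With RLE 1 was lost and 0 were gained, with the replicate block 1 and 4, and with fry 9 and 16, and 0 reversed. Named genes were followed under RLE, the replicate block, DESeq2 and each library left out. Of 8237 such values, 7264 kept their call, 973 lost it and 0 reversed, and the named calls kept under all of these were 92 of 116, 91 of 114, 39 of 74, 47 of 91, 39 of 97 and 93 of 116. The replicate block gave 2528, 2084, 487, 1046, 1292 and 2861 calls, 3465 for any difference and r of 0.839 and 0.824, and 39 of 917 values of named genes lost their call. Libraries with the same number had r of -0.144 to 0.0938 over 18 pairs, 0 of them over 0.1, and 3 of 12 libraries correlated best with their own number, so the numbers were not taken as pairs.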

Other observations

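Lists given for KRAS G12V against vector also passed in other comparisons, where higher or lower is the direction of the list test and most members were not called in some lists. In SOS1 WT against vector, cholesterol synthesis and uptake genes were lower, 0 higher and 3 lower of 20 (0 and 5 adjusted over the list alone) (camera adjusted p = 7.48e-05, adjusted p = 0.495 with an estimated correlation). Fatty acid synthesis genes were lower as well, 0 higher and 3 lower of 11 (1 and 6 adjusted over the list alone) (camera adjusted p = 8.06e-04, adjusted p = 0.334 with an estimated correlation), and EMT regulators higher, 4 higher and 0 lower of 11 (6 and 0 adjusted over the list alone) (camera adjusted p = 0.00502, adjusted p = 0.108 with an estimated correlation). Also in that comparison, TGF-beta response genes were lower, 2 higher and 4 lower of 15 (3 and 8 adjusted over the list alone) (camera adjusted p = 8.33e-04, adjusted p = 0.180 with an estimated correlation), and matrix proteases and inhibitors higher, 3 higher and 0 lower of 16 (7 and 1 adjusted over the list alone) (camera adjusted p = 7.73e-04, adjusted p = 0.266 with an estimated correlation). Mitosis genes passed as lower with no member called by edgeR, 0 higher and 0 lower of 20 (0 and 0 adjusted over the list alone) (camera adjusted p = 0.0114, adjusted p = 0.545 with an estimated correlation; lost at camera adjusted p = 0.0531 to 0.0861 without vector 1 or vector 3). DNA replication genes were lower in that comparison, 0 higher and 3 lower of 22 (0 and 3 adjusted over the list alone) (camera adjusted p = 3.44e-04, adjusted p = 0.495 with an estimated correlation), and higher in SOS1 N233Y than in SOS1 WT, 3 higher and 0 lower of 22 (3 and 0 adjusted over the list alone) (camera adjusted p = 0.0110, adjusted p = 0.611 with an estimated correlation; lost at camera adjusted p = 0.105 without SOS1 N233Y 3). SOS1 N233Y cells were lower than SOS1 WT cells in growth factor receptors, 0 higher and 3 lower of 11 (0 and 6 adjusted over the list alone) (camera adjusted p = 0.0113, adjusted p = 0.125 with an estimated correlation), ATF4 and unfolded protein response genes, 0 higher and 5 lower of 21 (0 and 5 adjusted over the list alone) (camera adjusted p = 0.00703, adjusted p = 0.495 with an estimated correlation), and contractile genes, 0 higher and 6 lower of 14 (0 and 6 adjusted over the list alone) (camera adjusted p = 0.00292, adjusted p = 0.470 with an estimated correlation). In KRAS G12V against SOS1 N233Y, contractile genes were higher, 4 higher and 0 lower of 14 (5 and 1 adjusted over the list alone) (camera adjusted p = 0.00138, adjusted p = 0.431 with an estimated correlation), and so were NRF2 targets, 4 higher and 0 lower of 16 (5 and 1 adjusted over the list alone) (camera adjusted p = 0.0212, adjusted p = 0.400 with an estimated correlation; lost at camera adjusted p = 0.0528 to 0.213 without SOS1 N233Y 1 or KRAS G12V 1). Interferon-stimulated genes were lower in KRAS G12V than in SOS1 WT, 0 higher and 4 lower of 5 (0 and 5 adjusted over the list alone) (camera adjusted p = 0.0395, adjusted p = 0.188 with an estimated correlation; lost at camera adjusted p = 0.0568 to 0.0755 without SOS1 WT 2 or KRAS G12V 2). In the same comparison, ERK feedback genes were higher, 12 higher and 1 lower of 16 (12 and 1 adjusted over the list alone) (camera adjusted p = 5.95e-06, adjusted p = 0.0776 with an estimated correlation), as were EGF receptor ligands and growth factors, 8 higher and 3 lower of 12 (8 and 3 adjusted over the list alone) (camera adjusted p = 0.0131, adjusted p = 0.319 with an estimated correlation), DNA replication genes, 8 higher and 0 lower of 22 (10 and 0 adjusted over the list alone) (camera adjusted p = 0.00428, adjusted p = 0.573 with an estimated correlation), and glycolysis genes, 10 higher and 1 lower of 18 (10 and 1 adjusted over the list alone) (camera adjusted p = 0.0495, adjusted p = 0.605 with an estimated correlation; lost at camera adjusted p = 0.0723 to 0.138 without SOS1 WT 1, SOS1 WT 2, KRAS G12V 1 or KRAS G12V 3). Growth factor receptors were lower, 0 higher and 7 lower of 11 (0 and 7 adjusted over the list alone) (camera adjusted p = 9.23e-05, adjusted p = 0.0666 with an estimated correlation), as were YAP-TEAD targets, 1 higher and 10 lower of 14 (1 and 11 adjusted over the list alone) (camera adjusted p = 5.95e-06, adjusted p = 0.144 with an estimated correlation), TGF-beta response genes, 1 higher and 6 lower of 15 (2 and 6 adjusted over the list alone) (camera adjusted p = 0.0312, adjusted p = 0.334 with an estimated correlation; lost at camera adjusted p = 0.0501 to 0.0849 without SOS1 WT 2, KRAS G12V 1 or KRAS G12V 2), and matrix proteases and inhibitors, 3 higher and 9 lower of 16 (4 and 9 adjusted over the list alone) (camera adjusted p = 9.54e-05, adjusted p = 0.207 with an estimated correlation). The median, mean and direction of the test differed in sign in uncalled lists as well. This held for SOS1 N233Y against SOS1 WT in immediate early, glycolysis, NRF2 and protease genes, and for KRAS G12V against SOS1 N233Y in EGF receptor ligand, mitosis, integrin and EMT genes. It also held for SOS1 WT against vector in p53 targets and cytokines, and for KRAS G12V against SOS1 WT in immediate early, fatty acid and contractile genes.

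Of the markers of other cell types, Lpl was lower (-1.63, SE 0.28, edgeR adjusted p = 2.96e-04) and Sox9 higher (0.52, SE 0.10, edgeR adjusted p = 0.00175) in SOS1 WT than in vector. Lpl was lower and Sox9 higher in SOS1 N233Y (-2.81, SE 0.47, edgeR adjusted p = 4.88e-05 and 0.59, SE 0.10, edgeR adjusted p = 6.57e-05) and KRAS G12V (-1.94, SE 0.42, edgeR adjusted p = 5.64e-04 and 0.59, SE 0.10, edgeR adjusted p = 2.49e-05) than in SOS1 WT. Runx2 and Flt1 were called higher in SOS1 N233Y than in SOS1 WT (0.47, SE 0.15, edgeR adjusted p = 0.0342 and 0.93, SE 0.26, edgeR adjusted p = 0.0151) but lost their calls (Runx2 adjusted p = 0.0568 to 0.170 without SOS1 WT 1, SOS1 WT 2, SOS1 WT 3, SOS1 N233Y 2 or SOS1 N233Y 3, and 0.144 with DESeq2, and Flt1 adjusted p = 0.0510 to 0.109 without SOS1 WT 1, SOS1 WT 3 or SOS1 N233Y 2, and 0.0596 with DESeq2). The same held for KRAS G12V against SOS1 WT (0.45, SE 0.15, edgeR adjusted p = 0.0185 and 0.70, SE 0.27, edgeR adjusted p = 0.0466, with Runx2 adjusted p = 0.102 to 0.119 without SOS1 WT 1 or KRAS G12V 3, and 0.0896 with DESeq2, and Flt1 adjusted p = 0.0539 to 0.163 without SOS1 WT 1, SOS1 WT 2, SOS1 WT 3, KRAS G12V 1 or KRAS G12V 2, and 0.117 with DESeq2).

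Genes called in KRAS G12V against SOS1 N233Y could be sorted by their calls against vector. Of 1431 such genes, leaving out Sos1 and Kras, 270 were called the same way from vector in both groups, 17 in opposite ways, 458 in KRAS G12V alone, 290 in SOS1 N233Y alone and 396 in neither. The log2 fold changes of SOS1 WT against vector and of KRAS G12V against SOS1 N233Y, which share no library, correlated with r = -0.377 across genes, with a simulated mean of -0.00147. Of the 519 genes called in the former, 226 were called the opposite way in the latter, and 3 higher and 7 lower in both, with 17.0 and 20.9 for independent lists.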
